A study of Homo sapiens with 12 samples.

How the data were processed

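RNA of 12 cultures of primary human trabecular meshwork cells, from 3 donor strains called strain 1 to 3 here, was measured on Clariom D arrays, each culture on its own array. Per the labels' protocols, cells were transfected with 5 pmol of siRNA, stretched for 24 hours from 72 hours after transfection, and 5 µg of total RNA were hybridised. The extraction protocol in the labels also names 72 hours as the time at which the cells were washed, so the time of collection is not settled. The deposited values are on a log2 scale, from 2.17 to 19.90, as the values themselves show. The method of background correction and normalization the authors used is not given in the sources used here. Partek is named in the submitters' processing notes, without a version.

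The deposited file holds 138745 rows (transcript clusters). Of these, 36176 were listed with 1 gene symbol, 1119 with several and 101450 with none, and rows with several were not named. The gene numbers of 25516 of the single-symbol rows were found in the list of genes of assembly GRCh38.p14, which was used for current symbols and gene classes only; other rows kept the symbol of the array's annotation. After 2995 control rows were left out, 33616 symbols remained, each represented by its cluster with the highest mean, and the 23119 genes with a mean above 4.20, the median of all row means, were tested. A gene was called below background on an array where its value lay under the 95th percentile of that array's 612 negative-control rows. For ATG5 and ATG7, where all siRNA arrays were, a lower bound of the fold was computed with those values raised to that percentile.

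Groups were compared with limma (version 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8), by lmFit on the 4 group means over all 12 arrays and eBayes with a mean trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 7 contrasts: stretch within each transfection, the siRNAs within each stretch state, the difference between stretch responses, and both effects averaged. This model without a strain term gave the main result, with 8 residual degrees of freedom. Because arrays of the same number in the labels come from the same donor strain, the pairing is set by the design, and the model with strain as a replicate block (6 residual degrees of freedom) is printed beside it for the counts of genes and for the number of lists past the test. Deviations from the group means correlated between 0.39 and 0.80 for the 18 pairs of arrays of the same strain and between -0.51 and -0.10 for the 36 pairs of different strain and group. The first and second principal components, with 34.8% and 24.7% of the variance, each had 97.6% of their own variance between strains. Negative-control medians were 4.70 to 5.15 in strains 1 and 2 and 4.24 to 4.33 in strain 3. The control non-stretched array of strain 1 correlated least with the other arrays of its strain (mean r of 0.979, against 0.984 to 0.990 for the other 11 arrays).

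Gene lists were tested with camera at a preset inter-gene correlation of 0.01, and also with an estimated correlation, with the block, and with fry, which tests whether a list's genes move 1 way on balance. Of 32 lists of 856 genes in all, 23 of processes and 9 of cell types, 31 had at least 5 tested members, with 743 genes tested; the melanocyte list had 3 and was not tested. With an estimated correlation 0 of 31 lists passed in any contrast, with or without the block. Adjustment over a list alone used the p-values of its members. Whether strains responded differently to stretch or to the siRNAs was tested after the data were seen, by strain-by-treatment terms over the 12 arrays with 4 residual degrees of freedom. In this test the 2 transfections or the 2 stretch states of a strain serve as its replicates. The averaged contrasts of the block fit likewise take the 2 pairs of arrays of a strain as separate. Their p-values and SEs therefore do not measure the spread of responses between donors alone. For ATG5 and ATG7 the transfection label was permuted within the 6 pairs of strain and stretch state, exactly. The contrasts, the main model, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named ATG5 and ATG7 in every contrast; the 12 highest and 12 lowest called genes by log2 change with the same direction in 3 strains (6 and 6 in the averaged contrasts), taken from the strain-block fit where the main model called too few; where that fit called fewer than 10, the 5 highest and 5 lowest by its statistic, as values; and up to 4 members of a described list with the smallest p. Pseudogenes, gene models without an established name and sex-linked marker genes were left out of it. How gene models without a name were recognised was narrowed after results had been seen, to match the rule as written, which let antisense genes be named.

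Alternatives covered the strain block, fixed or random, filters on dim genes, the treatment of several clusters per gene, quantile normalization and median centring, variance models, array weights, fitting the arrays of a contrast alone, other thresholds, and leaving out each strain and each array. The models were tested on simulated data with the real strain means and residual spread of 23119 genes, with 50 genes changed at each of 4 folds. For stretch in control cells, 4-fold changes were recovered for 60% of 50 genes without a strain term and 86% with the block, and 2-fold changes for 10% and 26%. For the siRNAs averaged over stretch states, 2-fold changes were recovered for 38% of 50 genes without a strain term and 68% with the block, with 1 and 8 unchanged genes called. In the same contrast camera called 10 of 10 simulated lists that moved and 0 of 40 that did not, at either correlation; the simulated genes varied independently, which members of real lists need not. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.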

Results

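Primary human trabecular meshwork cells, the cells of the tissue through which aqueous humour leaves the eye, were grown from 3 donor strains. Each strain was transfected with a non-targeting control siRNA or with siRNAs against ATG5 and ATG7, which encode proteins needed to attach LC3 to the growing autophagosome membrane. Cells were then kept still or stretched cyclically by 15% at 1 cycle per second for 24 hours. Total RNA of each of the 12 cultures was hybridised to its own Clariom D array, which gave 4 groups with 3 arrays each, 1 per strain. The array medians lay between 4.19 and 4.26 on the log2 scale, and the 95th percentile of the negative-control probes lay between 6.55 and 7.81. The number of arrays, 3 per group, limits the precision of every value.

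The siRNAs lowered both of their targets. ATG5 (Entrez 9474) had a mean signal of 9.47 ± 0.54 (SD, n = 6) in the control arrays and 6.71 ± 0.41 (SD, n = 6) in the ATG5/ATG7 siRNA arrays, a log2 change of -2.76 that leaves 14.8% of the signal. ATG7 (Entrez 10533) had a mean of 10.07 ± 0.26 (SD, n = 6) in control arrays and 6.65 ± 0.55 (SD, n = 6) with the siRNAs, a log2 change of -3.42 that leaves 9.3%. Both genes were lower in 6 of 6 pairs of arrays of the same strain and stretch state, and the exact two-sided permutation p of each was 0.03125 over 64 arrangements, the smallest this design allows. All 6 siRNA arrays read both genes below the 95th percentile of their own negative controls, so the drop is a bound, at least 4.76-fold for ATG5 and at least 7.18-fold for ATG7. With stretch ATG5 was at 0.63 in control cells and -0.08 in siRNA cells, and ATG7 at 0.23 and 0.16. None passed, nor did the differences of -0.71 and -0.07 or the averages of 0.27 and 0.19.

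**Figure D1:**
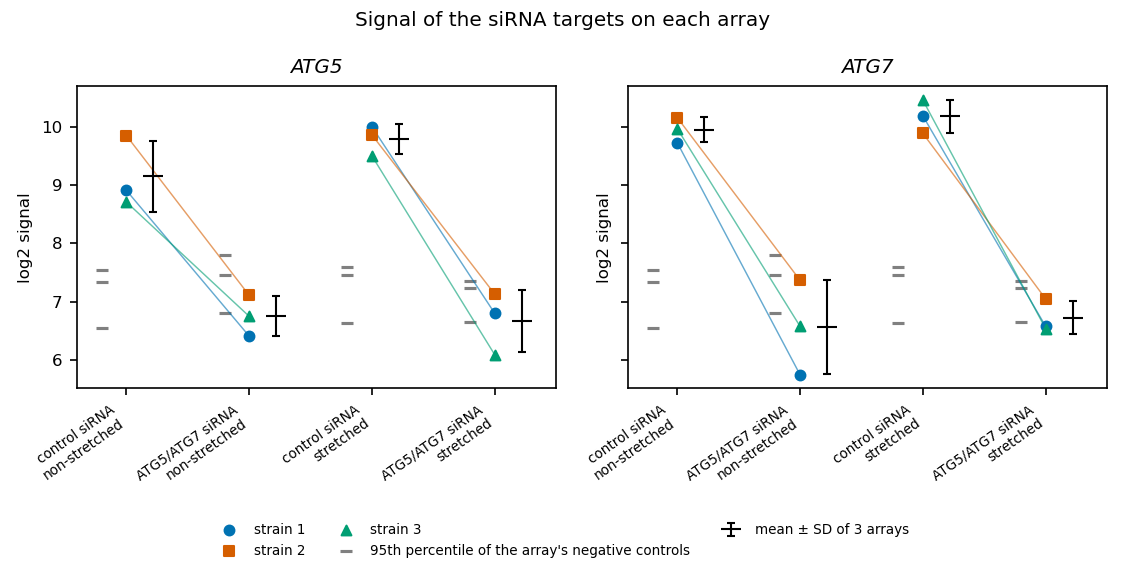
Signal (log2) of ATG5 and ATG7 on each of the 12 arrays, with 1 marker shape per strain, lines that join arrays of the same strain and stretch state, black bars for the mean ± SD of 3 arrays, and grey ticks for the 95th percentile of each array's negative controls. All 6 lines of each gene slope downward, and the 6 ATG5/ATG7 siRNA arrays lie below their grey ticks.

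The first comparison asked which genes responded to cyclic stretch in cells with the control siRNA. Sterol synthesis genes shifted upward, and by camera immediate early genes shifted downward. The cholesterol biosynthesis list had a median log2 change of 0.81, with 24 of 24 members above 0 (camera adjusted p = 6.62e-16, and adjusted p = 0.268 with an estimated correlation). HSD17B7, a 3-ketosteroid reductase of sterol synthesis, went from 8.28 ± 0.48 to 10.24 ± 0.38 (SD, n = 3). ACAT2, the cytosolic acetoacetyl-CoA thiolase, went from 11.21 ± 0.42 to 12.86 ± 0.27 (SD, n = 3). The immediate early list had a median of -0.19 with 10 of 27 members above 0 (camera adjusted p = 0.0042, and adjusted p = 0.268 with an estimated correlation). It did not pass by fry with the block (adjusted p = 0.428). Its member EGR1, a growth-factor-induced transcription factor, had a log2 change of -2.37 ± 0.46 (SE of the strain-block fit). Endoplasmic reticulum chaperone genes had a median of 0.36 (adjusted p = 6.05e-05, and adjusted p = 0.268 with an estimated correlation), with CRELD2 at 1.54 and PDIA4 at 1.28, and heat shock protein genes a median of 0.35 (adjusted p = 0.0029, and adjusted p = 0.268 with an estimated correlation). Targets of NRF2, the transcription factor of the oxidative stress response, had a median of -0.35 (adjusted p = 0.0029, and adjusted p = 0.872 with an estimated correlation), but 0.31 in strain 3, where 21 of 32 were higher.

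Over all genes tested no single gene passed with all 3 strains in this comparison. limma called 0 of 23119 genes at an adjusted p under 0.05, both without a strain term and with strain as a replicate block, and 0 with strain as a random block. At an unadjusted p under 0.05 there were 713 genes without a strain term and 1996 with the block, where chance alone gives 1156. Without strain 3 the block fit called 25, and over protein-coding genes alone, a setting chosen after the data were seen here and below, it called 1. Adjusted over the list alone, 16 of 24 cholesterol genes rose in the strain-block fit and 7 of 24 without it, against 0 over all genes tested in either fit. The 5 genes with the highest block statistic and the same direction in 3 strains were ACAT2 (log2 change 1.65, block adjusted p = 0.0586), HSD17B7 (1.96), ATOH8 (2.09, below background on 2 of 3 non-stretched arrays), FDPS (1.18) and GRAMD2B (1.71). The 5 lowest were EPGN (-2.60), an EGF-family ligand, SLC7A11 (-1.27) and SLC3A2 (-0.81), the light and heavy chains of the cystine transporter, DGKI (-1.37) and EGR1. Of 31 tested lists, 6 shifted up and 4 down, 10 passed with the strain block, and 0 did with an estimated correlation. The lowest camera adjusted p with an estimated correlation was 0.268, and 0.149 with the block.

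In cells with the ATG5/ATG7 siRNAs, targets of NRF2 were lower with stretch as a group. The difference between transfections for this list passed with the strain block (adjusted p = 0.0102) but not without it (adjusted p = 0.0989) or with the block and an estimated correlation (adjusted p = 0.802). In the siRNA cells the list had a median log2 change of -0.69 with 1 of 32 members above 0 (camera adjusted p = 9.18e-10, and adjusted p = 0.393 with an estimated correlation). HMOX1, haem oxygenase 1, went from 12.82 ± 1.09 to 9.80 ± 1.38 (SD, n = 3), lower in 3 of 3 strains, and SRXN1, sulfiredoxin, from 9.50 ± 0.80 to 7.26 ± 1.00 (SD, n = 3). The cholesterol list shifted up by a median of 0.43 (adjusted p = 7.27e-08, and adjusted p = 0.393 with an estimated correlation). Lists of oxidative phosphorylation genes (median -0.25, adjusted p = 7.47e-05) and of collagens and basement membrane genes (median -0.37, adjusted p = 0.0053) shifted down, both with adjusted p = 0.393 with an estimated correlation.

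limma again called 0 genes in the siRNA cells, with or without the strain block and with strain as a random block, and 464 genes without a strain term and 1336 with the block had an unadjusted p under 0.05. Over protein-coding genes alone the block fit called 2, both lower. In the strain-block fit 14 of 32 NRF2 genes fell adjusted over the list alone and 0 without the block, and 0 did over all genes tested. The 5 highest genes by the block statistic were ACAT2 (1.18), GPSM2 (1.24), H4C8 (0.99), EBP (0.87) and CAVIN4 (0.87), the last below background on every array and GPSM2 on all 3 non-stretched arrays. The 5 lowest were HMOX1 (-3.02, block adjusted p = 0.0680), SRXN1 (-2.24), SLC7A11 (-1.54), NKAIN2 (-1.85, below background on all 3 stretched arrays) and AGTR1 (-1.34), the angiotensin II type 1 receptor. Of 31 lists, 3 shifted up and 10 down, 15 passed with the strain block, and 0 did with an estimated correlation. The lowest camera adjusted p with an estimated correlation was 0.393, and 0.086 with the block.

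Averaged over both transfections, 4 of 24 sterol synthesis genes rose and 3 of 32 NRF2 targets fell with stretch over all genes tested when strain was a block. Neither list passed with the block and an estimated correlation (adjusted p = 0.054 and adjusted p = 0.244). With strain as a replicate block, limma called 6 genes higher and 15 lower, all 21 in the same direction in 3 strains, and 38 over protein-coding genes alone. Without a strain term it called 0 (653 genes at an unadjusted p under 0.05, 2044 with the block) and with strain as a random block 1. The genes with the largest rise in the block fit were ACAT2 (1.41 ± 0.15 SE, adjusted p = 0.0070), GPSM2 (1.36), HSD17B7 (1.26), the histone gene H4C8 (1.00), EBP (0.90), a sterol isomerase, and FDPS (0.88), farnesyl diphosphate synthase. Those with the largest fall were HMOX1 (-2.38 ± 0.29 SE, adjusted p = 0.0142), EPGN (-2.19), PDK1 (-1.66), a kinase that restrains pyruvate dehydrogenase, SRXN1 (-1.55), KCNJ6 (-1.51) and NKAIN2 (-1.51). GPSM2 lay below background in both non-stretched groups and NKAIN2 in both stretched groups. Without a strain term the adjusted p of ACAT2 was 0.756 and those of the other 11 were 0.9998. Without the control non-stretched array of strain 1 the block fit called 67 genes, among them all 21, and without strain 1, 2 or 3 it called 33, 0 and 74.

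Of the cholesterol genes, 20 of 24 rose adjusted over the list alone in the block fit and 7 without it, against 4 and 0 over all genes tested. The list's median was 0.59 (camera adjusted p = 3.38e-19, adjusted p = 0.102 with an estimated correlation, 0.054 with an estimated correlation and the block). The NRF2 list had a median of -0.53 (adjusted p = 5.59e-10, and adjusted p = 0.358 with an estimated correlation), and 15 of 32 members fell adjusted over the list alone in the block fit, 3 over all genes tested, among them SLC7A11 (-1.41, adjusted p = 0.0142). Its medians were -0.86, -0.32 and -0.08 in strains 1, 2 and 3, and in strain 3 15 members were higher and 17 lower. Immediate early genes had a median of -0.26 (adjusted p = 9.55e-06, and adjusted p = 0.102 with an estimated correlation); EGR1 (-1.94), DUSP5 (-1.27), DUSP6 (-1.28) and MYC (-0.78) fell adjusted over the list alone in the block fit, and 0 did over all genes tested. Among endoplasmic reticulum chaperones (median 0.17, adjusted p = 7.15e-05, and adjusted p = 0.248 with an estimated correlation), 5 of 25 rose adjusted over the list alone with the block, among them MANF (1.06) and PDIA4 (0.90). Of 31 lists, 5 shifted up and 8 down, and 14 passed with the strain block.

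**Figure D2:**
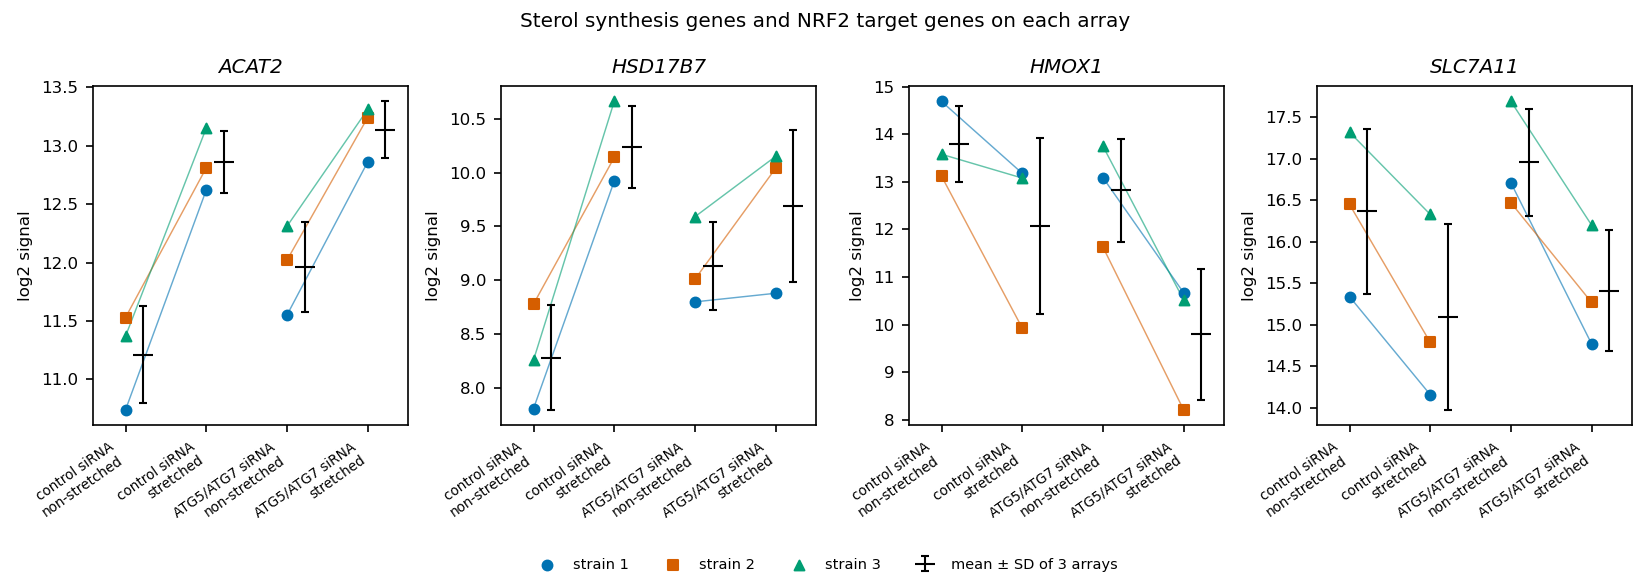
Signal (log2) of ACAT2, HSD17B7, HMOX1 and SLC7A11 on each array, with 1 marker shape per strain, lines that join the non-stretched and stretched array of a strain and transfection, and black bars for the mean ± SD of 3 arrays. All 6 lines rise for ACAT2 and HSD17B7 and fall for HMOX1 and SLC7A11; the signal of HMOX1 spans 8.21 to 14.69.

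Mitotic genes had medians of opposite sign in different strains under stretch. The cell cycle list had a median log2 change of 0.83 with stretch (camera adjusted p = 4.58e-10, and adjusted p = 0.620 with an estimated correlation), which joined 1.72 in strain 1, 1.56 in strain 2 and -0.63 in strain 3. Of its 41 members, 41 were higher with stretch in strain 1, 37 in strain 2 and 1 in strain 3. Adjusted over the list alone, 15 of 41 passed upward as an average of the strains in the block fit and 0 without it. Over all genes tested 0 did. As 1 of the 41 was higher in strain 3, this does not show a rise shared by the 3 donors. Replication-dependent histone genes followed the same order, with medians of 0.98, 0.62 and -0.70 (adjusted p = 6.80e-04 over the 3 strains, and adjusted p = 0.780 with an estimated correlation). A strain-by-stretch term, tested after these medians were seen, called 314 of 23119 genes, among them 28 of the 41 mitotic and 5 of the 31 histone genes. It also called 4 of the 32 NRF2 genes and 1 of the 36 interferon genes. The interferon list too had medians of both signs with stretch, 0.47, -0.22 and -0.70 in strains 1, 2 and 3. Between pairs of strains the mitotic list had adjusted p from 1.22e-50 to 5.13e-05 by camera, and from 0.417 to 0.850 with an estimated correlation. The same term for the siRNAs called 0 genes, which with 4 residual degrees of freedom does not show that the strains responded alike. For this term camera's preset correlation separated the interferon list of strain 3 from strain 1 (adjusted p = 5.44e-04) and strain 2 (adjusted p = 2.33e-09). Strains 1 and 2 were not separated (adjusted p = 0.328). With an estimated correlation no pair of strains was (adjusted p from 0.933 to 0.972).

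Among markers of cell types, those of the trabecular meshwork had a median of -0.32 with stretch (adjusted p = 0.0123, and adjusted p = 0.378 with an estimated correlation). MYOC, which encodes myocilin, had a log2 change of -1.13 ± 0.24 (SE), with 7 of 12 arrays below background, and CYP1B1 one of -0.84; both fell adjusted over the list alone in the block fit and neither over all genes tested (adjusted p = 0.112 and 0.136). The other 7 tested marker lists, those of vascular and Schlemm canal endothelium, corneal endothelium, surface and corneal epithelium, macrophages and leukocytes, Schwann cells and neurons, ciliary and smooth muscle and pericytes, and scleral and stromal fibroblasts, did not pass, with adjusted p from 0.280 to 0.867. Inflammatory and NF-kB target genes had a median of -0.22 (adjusted p = 0.0106, and adjusted p = 0.248 with an estimated correlation), with LIF at -1.46 and CXCL8 at -0.99, while BDKRB1, the bradykinin B1 receptor, was at 1.06.

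**Figure D3:**
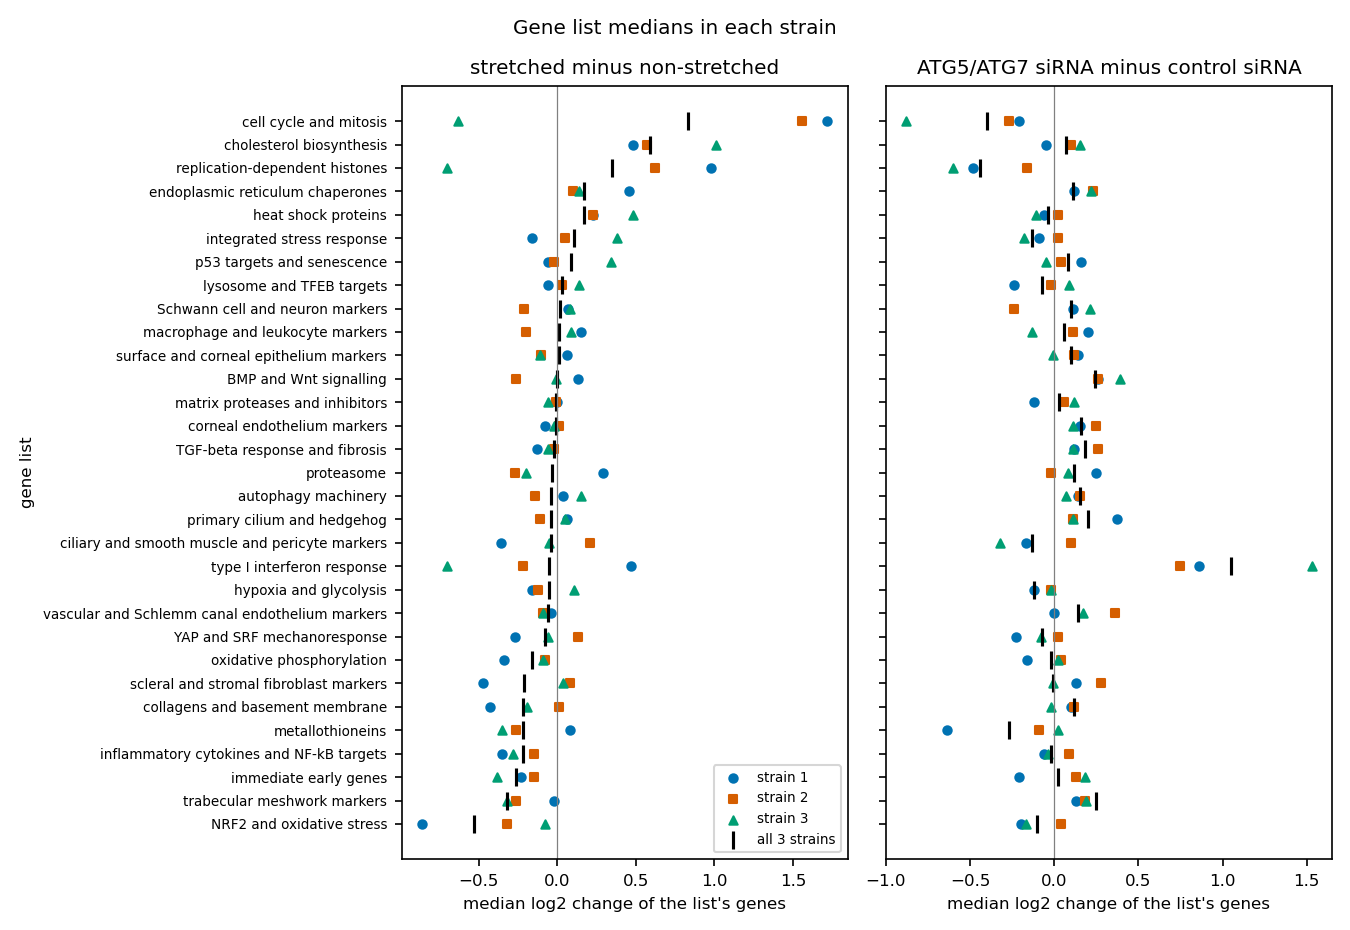
Median log2 change of the genes of each of the 31 tested lists, for stretch averaged over transfections on the left and for the ATG5/ATG7 siRNAs averaged over stretch states on the right, with 1 marker per strain and a black bar for all 3 strains. The cell cycle list lies at 1.72, 1.56 and -0.63 in the strains on the left, and the type I interferon list at 0.86, 0.75 and 1.53 on the right.

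The ATG5/ATG7 siRNAs were compared with the control siRNA first in non-stretched cells, to find what the loss of both transcripts went with at rest. Type I interferon response genes were higher as a group, with a median log2 change of 1.32 and 36 of 36 members above 0 (camera adjusted p = 3.08e-15, and adjusted p = 0.505 with an estimated correlation). IFIT1, an antiviral RNA-binding protein, went from 9.32 ± 2.42 to 12.46 ± 1.56 (SD, n = 3), a log2 change of 3.14 ± 0.55 (SE of the block fit), and DDX60 had a change of 1.96 and PARP14 of 1.65. Genes of the primary cilium and hedgehog signalling had a median of 0.37 (adjusted p = 7.73e-05, and adjusted p = 0.505 with an estimated correlation), with the intraflagellar transport gene IFT27 at 1.09 and below background on all 3 control arrays. Autophagy genes had a median of 0.29 with 28 of 38 above 0 (adjusted p = 0.0057, and adjusted p = 0.505 with an estimated correlation). Replication-dependent histone genes had a median of -0.36 (adjusted p = 0.0026, and adjusted p = 0.770 with an estimated correlation).

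limma called 1 gene in non-stretched cells, ATG7 (-3.38, adjusted p = 0.0307), and 3 with strain as a replicate block, ATG7, ATG5 (-2.40, adjusted p = 0.0088) and KCTD16 (1.57, adjusted p = 0.0413), a subunit of GABA-B receptor complexes. With strain 1, 2 or 3 left out the block fit called 0, 1 and 0 genes, and over protein-coding genes alone it called 23. Leaving out any of the 3 control arrays, or the siRNA array of strain 1 or 3, took the count without a strain term to 0. The other genes with the highest block statistic were EXTL3 (1.75, below background on 2 of 3 control arrays), GANAB (1.47), FGL2 (2.45) and OGFR (2.41), and those with the lowest were TBCD (-1.33), a tubulin folding cofactor below background on 2 of 3 siRNA arrays, AREL1 (-1.25) and NBPF15 (-1.05). Of the interferon genes, 28 of 36 rose adjusted over the list alone in the block fit and 1 without it, against 0 over all genes tested. Of 31 lists, 6 shifted up and 3 down, and 12 passed with the strain block. The lowest camera adjusted p with an estimated correlation was 0.505, and 0.263 with the block.

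Under stretch, the interferon genes were again higher with the siRNAs, with a median of 0.80 and 33 of 36 members above 0 (camera adjusted p = 2.33e-11, and adjusted p = 0.993 with an estimated correlation). IFI44L, below background on 2 of 3 control arrays, had a log2 change of 3.09 ± 0.71 (SE of the block fit) and IFIT1 one of 2.24 ± 0.55. Cell cycle genes had a median of -0.53 with 0 of 41 members above 0 (adjusted p = 0.0173, and adjusted p = 0.993 with an estimated correlation). limma called ATG5 (-3.11, adjusted p = 0.0318) and ATG7 (-3.46, adjusted p = 0.0246) and no other gene, and the same 2 with the strain block (adjusted p = 8.04e-04 for both). With strain 1, 2 or 3 left out the block fit called 2, 2 and 0 genes. Leaving out any 1 of the 6 arrays took the count without a strain term to 0, and leaving out the control non-stretched array of strain 1 took that with the block to 8. The remaining genes with extreme block statistics were MICAL2 (1.72), OGFR (2.26), CHST14 (1.48), TSC22D1 (1.45) and ZDHHC18 (1.99) on the high side, and TBCD (-1.61, below background on 2 of 3 siRNA arrays), PPIF (-1.68), the mitochondrial cyclophilin, and TXLNG (-1.35, below background on all 3 siRNA arrays) on the low side. In the block fit 8 of 36 interferon genes rose adjusted over the list alone and 0 over all genes tested. Of 31 lists, 1 shifted up and 3 down, and 8 passed with the strain block. The lowest camera adjusted p with an estimated correlation was 0.993, and 0.661 with the block.

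Averaged over stretch states, 6 of 36 interferon genes rose with the siRNAs over all genes tested when strain was a block, and 0 did without it. The list did not pass with an estimated correlation (adjusted p = 0.807, and 0.352 with the block). Without a strain term limma called ATG5 (adjusted p = 0.0031) and ATG7 (adjusted p = 6.85e-04) alone, with 1019 genes at an unadjusted p under 0.05. With strain as a replicate block it called 126 genes higher and 31 lower, all 157 in the same direction in 3 strains. Over protein-coding genes alone that fit gave 286 genes changed by ATG5/ATG7 siRNA averaged over stretch states. With strain as a random block it called 24 higher and 5 lower. The genes that rose most in the block fit were IFI44L (3.02 ± 0.50 SE, adjusted p = 0.0196), IFIT1 (2.69 ± 0.39, adjusted p = 0.0113), RSPO3 (2.57), a secreted enhancer of Wnt signalling, OGFR (2.34), RSAD2 (2.24), which encodes the antiviral protein viperin, and FGL2 (2.06). Besides both targets, those that fell most were ANKRD46 (-2.03), HMOX1 (-1.62 ± 0.29, adjusted p = 0.0314), TBCD (-1.47) and PPP3CC (-1.46), a catalytic subunit of calcineurin. Of the 157 genes 5 lay below background on every array. On the 6 control arrays RSAD2 and RSPO3 did so 4 times and IFI44L 3 times, as TBCD did 4 times on the 6 siRNA arrays. With strain 1, 2 or 3 left out the block fit called 11, 11 and 2 genes. Without a strain term the adjusted p of the 10 genes named above, both targets aside, lay between 0.207 and 1.0000.

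The interferon list had a median of 1.05, with 0.86, 0.75 and 1.53 in the 3 strains (camera adjusted p = 5.59e-21, adjusted p = 0.807 with an estimated correlation, 0.352 with an estimated correlation and the block). Adjusted over the list alone, 29 of 36 members rose in the block fit and 12 without it, against 6 and 0 over all genes tested. DDX60, below background on 3 of 6 control arrays, rose by 1.60 and PARP9 by 1.24. Histone genes had a median of -0.44 (adjusted p = 3.17e-05) and cell cycle genes one of -0.40 (adjusted p = 2.00e-04), both with adjusted p = 0.868 with an estimated correlation and with 0 members past the test adjusted over the list alone. The cell cycle medians were -0.21, -0.27 and -0.88 in strains 1, 2 and 3, and -0.07, 0.02 and -1.17 in non-stretched cells. The primary cilium list had a median of 0.20 (adjusted p = 0.0023, and adjusted p = 0.842 with an estimated correlation), and IFT27 (1.01, adjusted p = 0.0165, below background on 5 of 6 control arrays) alone of its 30 members rose. The autophagy list did not pass here (median 0.15, adjusted p = 0.146) or under stretch (median -0.06, adjusted p = 0.926). None of the 8 tested cell type marker lists passed without the block (adjusted p from 0.140 to 0.979). With it, vascular and Schlemm canal endothelium markers shifted up (adjusted p = 0.0122) and ciliary and smooth muscle and pericyte markers down (adjusted p = 0.0034), both with adjusted p = 0.352 with an estimated correlation and the block. Of 31 lists, 2 shifted up and 2 down, and 8 passed with the strain block.

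**Figure D4:**
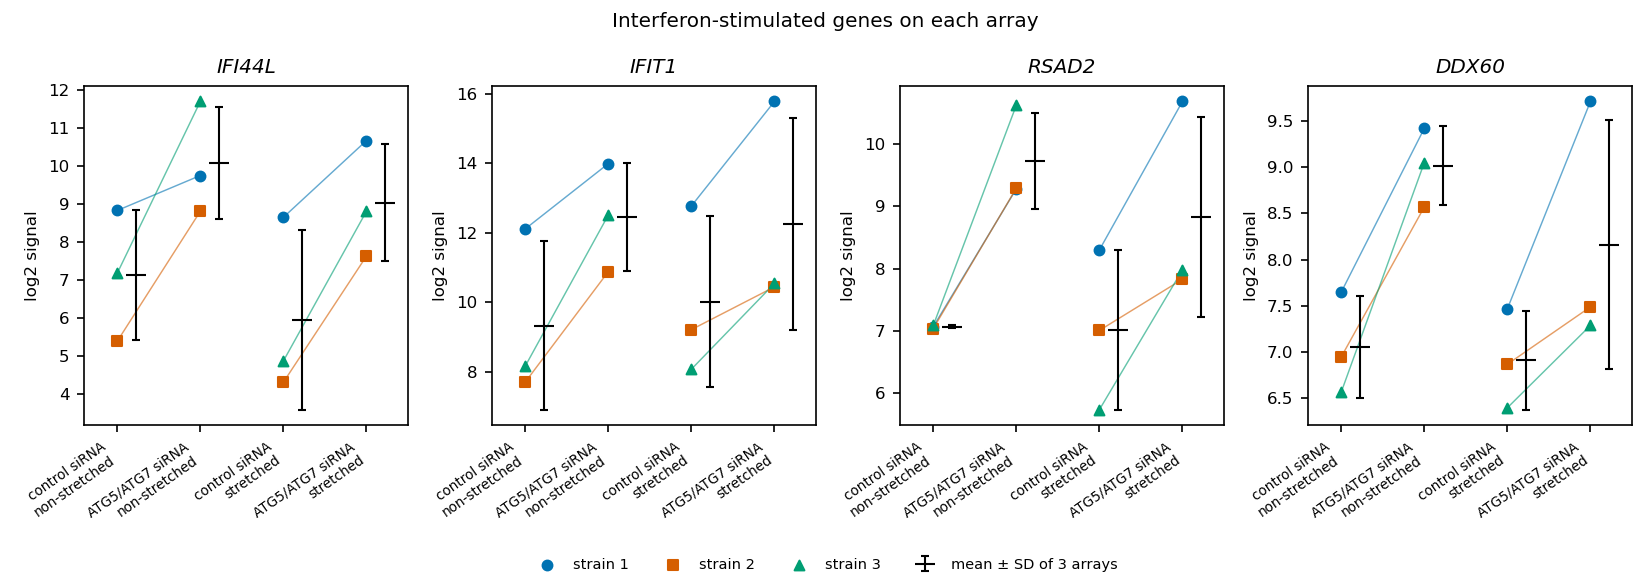
Signal (log2) of IFI44L, IFIT1, RSAD2 and DDX60 on each array, with 1 marker shape per strain, lines that join the control and the ATG5/ATG7 siRNA array of a strain and stretch state, and black bars for the mean ± SD of 3 arrays. All 6 lines of each gene slope upward, and IFIT1 spans 7.70 to 15.78 over the arrays.

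The last comparison asked whether the response to stretch differed between the transfections. Sterol synthesis, autophagy, primary cilium and p53 target genes had lower stretch responses in the siRNA cells as groups, with median differences of -0.50, -0.38, -0.41 and -0.46 (camera adjusted p = 0.0160 for the first 3 and 0.0464 for p53 targets, and adjusted p = 0.987 with an estimated correlation for all 4). The first 3 of these lists were already higher with the siRNAs in non-stretched cells, whose arrays both contrasts share (adjusted p = 0.0380, 0.0057 and 7.73e-05, and adjusted p = 0.749, 0.505 and 0.505 with an estimated correlation). The p53 targets were so with the strain block (adjusted p = 0.0154) but not without it (adjusted p = 0.0916) or with the block and an estimated correlation (adjusted p = 0.500). HSD17B7 had the smallest p of the cholesterol genes, with a difference of -1.40 ± 0.38 (SE of the block fit), and ATG4B, an LC3-processing protease, that of the autophagy genes, with -1.15 ± 0.48. ZMAT3, a p53 target, was at -1.28 ± 0.44. No member of these 4 lists passed adjusted over the list alone. limma called 0 genes with and without the strain block and with strain as a random block; 464 genes without a strain term and 1136 with the block had an unadjusted p under 0.05. The genes with the highest block statistic, ADPGK-AS1 (1.20), LRRC2-AS1 (0.94), CNGA3 (1.13) and CFAP92 (0.89), lay below background on every array, unlike PALMD (1.10). Of the lowest, RNF212 (-1.11), GPR174 (-1.24), PPP1R3F (-1.41) and CNMD (-1.24) did so too, unlike SUPT3H (-1.58), which did on all 3 control non-stretched arrays. With the strain block 11 lists passed in place of 4, among them NRF2 targets and interferon genes (adjusted p = 0.0320). With the block and an estimated correlation 0 lists passed (lowest camera adjusted p = 0.670), and without the block 0 did after quantile normalization. Across the 23119 genes, which are not independent replicates, the stretch responses of the 2 transfections had a Pearson r of 0.25. Spearman's rho was 0.15, and 51.4% of genes had the same sign. Agreement was also low between the siRNA effects without and with stretch (r of 0.33, rho of 0.19, 53.3% of the same sign). The filter on dim genes lay below the negative-control median of every array, so genes without signal above background are included. The sign of such genes may be noise. These values therefore cannot decide whether the siRNAs changed the response to stretch.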

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

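The tests of this part were fixed before the values were seen, except the strain-block fit of rows without a gene name and the strain-by-stretch term. That term, which asks whether stretch responses differed between strains, called 314 of 23119 genes. The stretch response of 4 gene lists also differed between the transfections by a test of the difference itself, with medians lower in the ATG5/ATG7 siRNA cells: -0.38 for autophagy machinery, -0.46 for p53 targets and senescence, -0.50 for cholesterol biosynthesis, and -0.41 for primary cilium and hedgehog genes. None of the 4 passed with an estimated correlation (adjusted p = 0.987 for each), and the strain medians of the cholesterol list were -0.57, -0.04 and -0.85.

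Rows of the array without a listed gene name were outside the comparisons of genes. When 66667 rows above the dim filter were fitted separately with strain as a block, 6 of the 41080 rows without a name passed for the siRNAs averaged over stretch states, 4 higher and 2 lower, and 0 passed for stretch averaged over transfections.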

How the results depend on the processing

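Settings that combine the strain block with protein-coding genes only, or with the control non-stretched array of strain 1 left out, and the list tests with a strain left out, were chosen after seeing the data. The cause was not tested for any change below except where fewer arrays or genes explain it. With strain as a replicate block the count was 3 for the siRNAs without stretch, 21 for averaged stretch and 157 for the averaged siRNAs, against 1, 0 and 2, and ATG5 without stretch (-2.40) passed; the block changed no other count of genes by over 1.5 times. With strain as a random block these counts were 2, 1 and 29. Testing all rows separately gave 0 for the siRNAs without stretch and 1 under stretch, and fitting only the arrays of the contrast gave 0 and 0. An unadjusted p under 0.05 with at least 1.5-fold gave 559 genes changed by stretch in control-transfected cells, 293 genes changed by stretch in ATG5/ATG7 siRNA cells, 793 genes changed by ATG5/ATG7 siRNA without stretch and 448 genes changed by ATG5/ATG7 siRNA under stretch. It gave 441 genes whose stretch response differed between transfections, 256 genes changed by stretch averaged over transfections and 524 genes changed by ATG5/ATG7 siRNA averaged over stretch states.

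Leaving out strains without a block gave 0 to 0 genes for the siRNAs without stretch and 0 to 0 under stretch, and 0 to 1 averaged; leaving out single arrays gave 0 to 1 without stretch and 0 to 0 under stretch. In these fits ATG7 ranged from -3.68 to -3.09 without stretch, ATG5 from -3.31 to -2.97 and ATG7 from -3.77 to -3.22 under stretch, and averaged ATG5 from -2.79 to -2.71. Each lost its call whichever strain was left out; averaged ATG7 lost it without strain 1 (-3.24) and strain 3 (-3.30) and kept it without strain 2 (-3.72). With the block, leaving out a strain gave 0 to 25 genes for stretch in control cells, 0 to 1 for the siRNAs without stretch, 0 to 2 under stretch, 0 to 1 for the difference, 0 to 74 for averaged stretch and 2 to 11 for the averaged siRNAs. Of the 21 genes 10, 0 and 7 were shared without strains 1, 2 and 3, and of the 157 genes 10, 11 and 2. With the block and the control non-stretched array of strain 1 left out the counts were 2 and 8 for the siRNAs without and under stretch, 67 for averaged stretch and 203 for the averaged siRNAs. Over protein-coding genes alone the block gave 1 and 2 genes for stretch in control and siRNA cells, 23 for the siRNAs without stretch, 38 for averaged stretch and 286 genes changed by ATG5/ATG7 siRNA averaged over stretch states.

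Of the 57 list shifts, 0 passed in any of the 7 contrasts with an estimated correlation, with or without the replicate block. Counts per contrast in this paragraph are of all 31 lists. With the block and the preset correlation 55 passed, and the counts were 8 for the siRNAs under stretch, 11 for the difference and 8 for the averaged siRNAs. By fry with the block 8 of the 57 passed. Over all 31 lists, fry gave 2 and 2 for stretch in control and siRNA cells. It gave 6 for the siRNAs without stretch, 0 for the siRNAs under stretch and 0 for the difference. Averaged stretch had 3 and the averaged siRNAs 1. Quantile normalization left 45 and took the difference to 0. Over protein-coding genes 45 passed, with counts of 8 and 8 for the siRNAs under stretch and averaged. Without the control non-stretched array of strain 1, 51 passed, with 8 under stretch, 12 for the difference and 8 averaged. Leaving out strains 1, 2 and 3 left 37, 47 and 43; the counts ranged from 8 to 15 for stretch in siRNA cells, 4 to 7 for the siRNAs under stretch, 4 to 11 for the difference, and 7 to 8 for the averaged siRNAs. Of 76 values of named genes, the siRNA effect on ATG5 and ATG7 aside, 23 that had not passed did so with the replicate block and 3 with the random block. The 23 were named because the replicate-block fit called them, so their passing there is set by the rule and is no separate result. Of the stretch values of the targets, none past the test, 4 changed sign with a strain left out. ATG5 in siRNA cells ranged from -0.32 to 0.21, ATG7 in siRNA cells from -0.18 to 0.40, averaged ATG7 from -0.03 to 0.44, and the difference for ATG7 from -0.30 to 0.16. The last was 0.02 after quantile normalization. Signal near background limits ATG5 and ATG7 folds in siRNA arrays to lower bounds.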

Other observations

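Tests of leukocyte RNA, of single strains, of the siRNA duplexes, of exchanged stretch labels in strain 3, of strain-by-stretch differences and of zinc finger genes were chosen after the result was seen. The siRNAs also moved single members of gene lists in the strain-block fit. Among autophagy genes CALCOCO2, a receptor for ubiquitin-coated bacteria and mitochondria, rose by 0.68 (adjusted p = 0.0437), while SQSTM1, which encodes the cargo receptor p62, fell by 0.62 on the log2 scale adjusted over the list alone (adjusted p = 0.0167 there and 0.0733 over all genes tested). Of the BMP and Wnt signalling genes, 5 of 26 passed upward adjusted over the list alone, among them RSPO3 and DKK2 (1.00), while BMP2 and RSPO2 lay below background on 10 and 9 of 12 arrays. The list passed with the block (adjusted p = 6.86e-04) and not without it (adjusted p = 0.140, and adjusted p = 0.842 with an estimated correlation). Of the endothelial markers ERG, FLT1 and TEK, at 1.09, 0.81 and 0.61, rose adjusted over the list alone, and EMCN, which passed over all genes tested, lay below background on 12 of 12 arrays. The endothelial genes PECAM1, VWF, CD34, CLDN5, TIE1, ESAM and FLT4 also lay below background on 12 of 12 arrays. Among lysosomal genes NPC1, the cholesterol exporter of late endosomes, fell by 0.73 on the log2 scale adjusted over the list alone (adjusted p = 0.042).

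Interferon genes were higher with the siRNAs by camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.807, and 0.352 with the block). Leukocyte RNA cannot be told apart from a response of the cells: the leukocyte list had a median change of 0.057 against 1.05, but 14 of its 15 members lay below background on at least 11 of 12 arrays and the other, CD68 (mean 12.18), was 0.31 higher. No single strain carried the shift, since the lowest median with a strain left out was 0.80, and its median lay far above random lists matched on mean signal, whose 95th percentile was 0.09 (percentile 100 of 10000 lists). The duplexes themselves and the loss of ATG5 and ATG7 cannot be told apart, because each arm had 1 siRNA mixture; IFNB1 had a difference of -0.10 and lay below background on 12 of 12 arrays. A response of the cells to the loss of autophagy proteins may underlie the shift and remains an untested hypothesis.

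NRF2 targets were lower with stretch. A shift of bright genes would not produce it, since the list's median lay at percentile 0.0 of 10000 matched random lists, whose 5th percentile was -0.07; without the control non-stretched array of strain 1 the median was -0.39 against -0.53, and after quantile normalization -0.54. An effect of stretch on NRF2 activity, which was not measured, is a candidate explanation and an untested hypothesis. It is limited by the strains, whose medians were -0.86, -0.32 and -0.08, and by the adjusted p of 0.358 with an estimated correlation.

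Mitotic genes had medians of 1.72, 1.56 and -0.63 in strains 1, 2 and 3 under stretch. Exchanged stretch labels in strain 3 would turn its cholesterol genes downward, yet their median there was 1.01, with 22 of 24 higher. It was 1.43 in control cells and 0.58 in siRNA cells, so such an exchange does not account for the pattern. The NRF2 median of strain 3, -0.08, joined 0.31 in control cells and -0.60 in siRNA cells. As these point opposite ways, the NRF2 list does not decide this. A shift of bright genes in strain 3 is also excluded (percentile 0.0 of matched random lists). The strain-by-stretch term passed for 28 of the 41 genes, while the list did not pass between any 2 strains with an estimated correlation. How dense or how far cycling each strain's cultures were is not recorded in the labels. Each strain has only its own arrays, so a difference between donors cannot be told apart from one between runs of culture or hybridisation. Negative-control medians were also lower in strain 3 (4.24 to 4.33, against 4.70 to 5.15). What may be the reason stays open.

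Other groupings of the arrays were fitted in the same way. For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05: the true split gave 0 genes for stretch in control cells and 0 in siRNA cells, as did all 10 splits of each. It gave 1 gene for the siRNAs without stretch and 2 under stretch, where the highest other split gave 0 and 1 split, the true one, reached the count. With 12 arrays fitted as 2 groups of 6, 100 of 100 splits gave at least the 0 genes of the difference between stretch responses and of averaged stretch, which any split must and which says nothing of chance. For the averaged siRNA effect 4 of 100 gave at least its 2 genes. These splits ignore the pairing by strain, so chance is judged by the exchanges within pairs. The highest other split in each gave 708 genes and kept 2 strains whole on opposite sides, which points to the strains as the main structure of the samples. With strain as a block, 1 of the 32 ways to exchange labels within pairs reached the 157 genes of the averaged siRNA effect. This was the true one, and the next gave 1 gene. That share is the smallest that 32 exchanges allow. The 2 pairs of a strain are also exchanged as if independent, so the result argues against chance but does not exclude it. For averaged stretch 2 gave at least its 21 genes. The one besides the true labels, with the labels of strain 3 exchanged in both transfections, gave 56. That exchange sets strain 3 against strains 1 and 2, between which the strain-by-stretch term called 314 genes. Its calls may thus reflect differences between strains. The exchanges therefore cannot decide whether the 21 genes stand out from chance.

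A hypothesis, noticed among the called genes themselves, was that zinc finger genes are enriched among those raised by the siRNAs. With the block, 13 of 496 tested zinc finger genes (2.6%) were called higher, against 111 of 13954 other protein-coding genes (0.8%; Fisher's exact two-sided p = 3.336e-04). Their median change was 0.24, at percentile 100 of matched random lists, and 0.33, 0.20 and 0.22 in the 3 strains; it was 0.40 without stretch and 0.08 under stretch. ZNF616 (1.63) and ZKSCAN1 (1.33) had the largest changes. With the block camera gave p = 1.69e-18 at the preset and p = 0.0191 at an estimated correlation. Fisher's test and the random lists treat genes as independent, and the p restates the observation that prompted it, so it is no independent evidence and the pattern may not hold in other data.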
